A study of Homo sapiens with 54 samples.

How the data were processed

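RNA of cultured 16Lu cells, a human adult lung fibroblast line, was hybridised to 54 Affymetrix human genome arrays (type U133, A version). Per the labels, a separate frozen stock was thawed for each experiment, confluent cells were held in a serum-free defined medium for 24 h, and they then received vehicle, carbon black nanoparticles (CBNP) or multi-walled carbon nanotubes (MWCNT) at 10 µg per cm2, with or without interleukin-13 (IL-13), for 4, 24 or 48 h. RNA was purified so that most particles stayed behind in the organic phase, and biotin-labelled cRNA was made from it, per the labels' protocols. The 18 groups hold 3 arrays each, and group and time come from the labels alone. The labels do not tie the frozen stocks to single arrays, and all arrays come from 1 cell line, so p-values here measure the spread between arrays of that line.

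The values analysed are those the authors deposited in the series matrix, 1 value per probe set and array, with 22277 probe sets and 0 missing values. They lie on a log scale with each array centred near a mean of 0, and whether the base is 2 or e could not be settled from the values. The software, background correction and normalization behind the deposited log values are not given in the sources used here. Differences are therefore given in deposited log units, where 1 unit is 2.0-fold if the values are log2 and 2.72-fold if they are natural logs. The tests had been planned for log2 values, and they do not depend on the base. The brightest and dimmest probe sets lay 5.08 units apart in their means over arrays. Because it is unknown whether background was subtracted, differences of dim genes may be compressed. The number of arrays limits the precision of each value, and hybridisation depth has no counterpart of a read count. The median correlation between a pair of arrays was 0.987 and the lowest was 0.95, and 0 arrays were duplicates of another.

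Probe sets were named through the platform annotation supplied with the values. Of the 22277, 62 were controls, 19070 had 1 gene symbol, 1043 had several and 2164 had none. Those with several or no symbol were not named or tested. The gene identifiers of 19058 probe sets were found in the RefSeq gene table, which updated 0 symbols. Of 11963 genes, 4310 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all arrays. A gene was tested if at least 3 arrays reached the 40th percentile of all values, -0.42 log units, which left 8737 genes.

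Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level) as 18 group means over all 54 arrays, with 36 residual degrees of freedom, no block and no covariate. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The comparisons were the IL-13 label in vehicle cells at each time, each particle against vehicle at each time in each IL-13 state, 24 and 48 h against 4 h in vehicle cells without IL-13, the same differences averaged over conditions, MWCNT against CBNP, and the interaction of each particle with IL-13. A pooled SE is given for each fitted difference. Another 2 differences, each particle's effect at 48 h minus that at 4 h, were added after the data had been seen. Fixed before the data were examined were the groups, comparisons, tests, filter, most alternatives, 25 gene lists and the rule for the genes named. That rule took, for averaged comparisons, the 12 genes with the largest increase and the 12 with the largest decrease past the threshold and of the same sign in every condition. By time it took 8 increases and 5 decreases whose arrays did not overlap between groups, for each interaction the 10 smallest p-values, for each list up to 4 members, and a fixed set of cytokine, matrix and stress genes. Genes named outside that rule are so described. CCL26 of the fixed set had no probe set with 1 symbol, and CXCL8 and PTGS2 were below the filter, so these genes are not analysed here.

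The gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. They cover the IL-13 and STAT6 response, chemokines, NF-kB feedback, fibrillar collagens, collagen modification, contractile genes, matrix proteases, the TGF-beta response, growth factors, NRF2 targets, metallothioneins, aryl hydrocarbon receptor targets, the unfolded protein response, heat shock, p53 targets, the cell cycle, cholesterol synthesis, interferon, immediate early genes, hypoxia, lysosomes and the serum response, and markers of epithelial, endothelial and leukocyte cells. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

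The numbers in the array titles form 3 runs of 18, each holding every group once, and the run number was checked as a pairing of arrays. Arrays of the same run deviated together from their group means, with r above 0.1 in 407 of 459 pairs (88.7%) and a median r of 0.435. Between arrays of different runs and groups the median was -0.208. The deviations of a group's 3 arrays cancel out, which forces this value to be negative when same-run values are positive. It is therefore no separate evidence of pairing. In 15 of the 17 comparisons of 2 groups every same-run pair exceeded 0.1. The exceptions were run 2 of CBNP against vehicle with IL-13 at 48 h (r 0.093) and run 2 of 48 h against 4 h (r 0.03). Of the first 3 principal components, the first held 30.6% of the variance and lay 86.9% between times, and the second held 14.8% and lay 75.1% between runs. The run numbers were therefore taken to pair the arrays. The main fit kept its planned form without a block and so ignored this pairing. A gene or list not called in it may be called with the run as a block. The value with the block is given beside counts that it moves by more than 1.5 times. It is also given beside most genes and lists in the text whose call it changes. The 3' minus 5' difference of the ACTB probe sets, a measure of RNA integrity, averaged -0.04 (SD 0.13) in vehicle, -0.091 (SD 0.096) in CBNP and 0.072 (SD 0.42) in MWCNT arrays (n = 18 each), with a highest value of 1.39 in an MWCNT array.

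Alternatives were quantile normalization, centring each array on its median, no filter, a stricter filter at the 60th percentile (6307 genes), the mean of all probe sets of a gene, eBayes without trend, a fit of the compared groups alone, the run as a block, and leaving out each array in turn. After the data had been seen, fits without 3 arrays of doubtful quality, with the ACTB and GAPDH differences as covariates, and with both the block and these covariates were added. The 3 arrays were MWCNT without IL-13 at 48 h replicate 2, vehicle without IL-13 at 4 h replicate 3 and vehicle with IL-13 at 48 h replicate 3. Leaving out 1 array of 3 keeps the pooled spread, so the remaining arrays are assumed to vary like the other groups. Under the other scalings the median of all genes moved by at most 0.0245 log units. The pipeline was tested on simulated data with 8737 genes. For MWCNT without IL-13 at 48 h, 38.8%, 91% and 98.5% of genes changed by 0.2, 0.4 and 0.8 units were recovered, with 2 false calls among 8537 unchanged genes. For MWCNT averaged over conditions 94%, 100% and 100% were recovered, with 3 false calls. The simulated arrays held the run effects, but their remaining noise was drawn independently for each gene. They lack any other correlation between genes, so recovery and false calls in the real arrays may differ from these.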

Results

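Transcript levels were measured in 16Lu human lung fibroblasts given vehicle, CBNP or MWCNT, each in cultures labelled with or without IL-13, at 4, 24 and 48 h, with 3 arrays in each of the 18 groups. MWCNT are fibre-like carbon particles, CBNP are near-spherical carbon particles used beside them at the same dose. IL-13 is a type 2 cytokine that acts on fibroblasts through its receptor and STAT6. By the title and design text, the question was how MWCNT alters fibroblast gene expression, with CBNP, IL-13 and time as further factors. All levels and differences are in deposited log units of unstated base. Each fold is therefore given for base 2 and for base e, and adjusted p-values are limma's.

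CCL11, the eosinophil-attracting chemokine eotaxin that IL-13 is known to induce in fibroblasts, was lower in the arrays labelled with IL-13. Over all exposures and times its mean was 0.48 with the label and 0.94 without it, a difference of -0.45 (SE 0.082, n = 27 arrays each, adjusted p = 0.0032). That is 1.37-fold lower if the base is 2 and 1.57-fold if it is e. The difference was negative in 9 of 9 conditions, from -0.81 to -0.085. It was also negative in 27 of 27 pairs of arrays of the same run, exposure and time, and was -0.45, -0.45 and -0.46 in the 3 runs. Because a known IL-13 target moved against its label, the groups are called arrays labelled with and without IL-13 throughout. In all 15 genes fell and 0 rose in the labelled arrays (385 genes at an unadjusted p under 0.05), against 47 and 2 with the run as a block. Of the 15, 5 had the same sign in all 9 conditions. Beside CCL11 these were PRR16 (-0.17, SE 0.031, adjusted p = 0.00341), the transcriptional cofactor DACH1 (-0.13, SE 0.027, adjusted p = 0.022), the scaffold protein PPFIBP2 (-0.11, SE 0.018, adjusted p = 0.00109) and the STAT-induced kinase PIM1 (-0.073, SE 0.015, adjusted p = 0.0198). The call of DACH1 ended without the 3 arrays of doubtful quality (adjusted p = 0.0654) and with the mean of all its probe sets (adjusted p = 0.0639). Over all alternatives its adjusted p ran from 2.87e-05 to 0.0654.

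**Figure D1:**
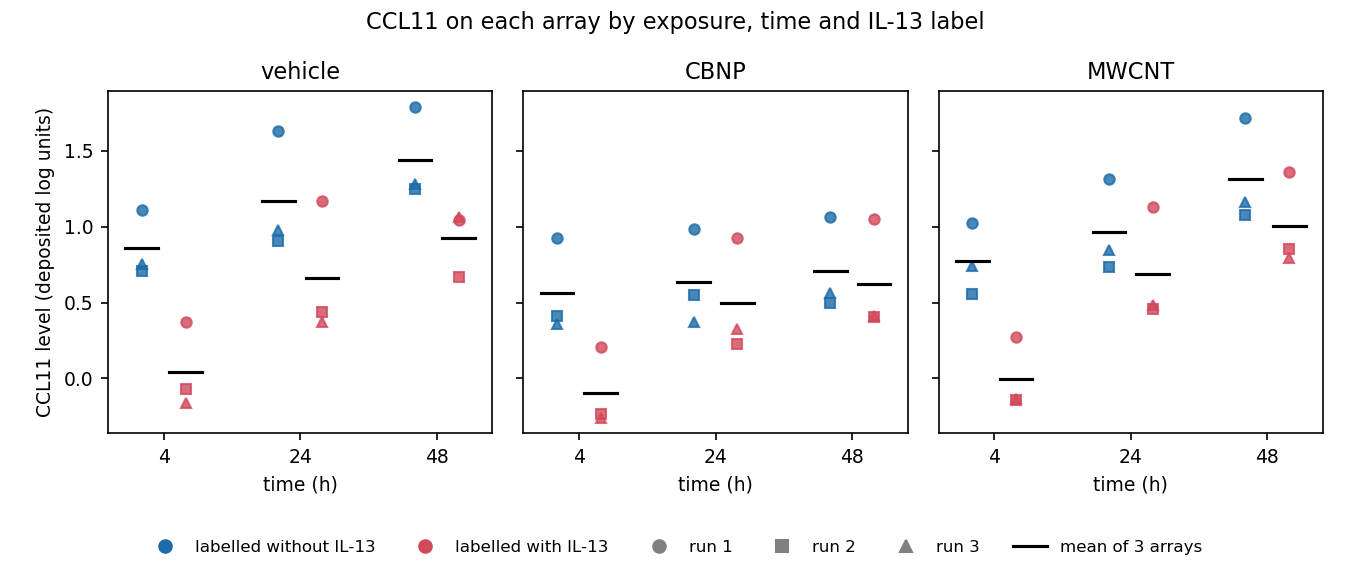
CCL11 level (deposited log units, y axis) of each of the 54 arrays by time in hours (x axis) in vehicle, CBNP and MWCNT cultures, coloured by IL-13 label, with the run as the marker and a bar at the mean of 3 arrays. At 4 h the vehicle means were 0.86 without and 0.045 with the label, and at 48 h the means without the label were 1.44 in vehicle and 0.71 in CBNP cultures.

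The IL-13 and STAT6 response list was lower as a set in the labelled arrays. Of its 18 members tested (of 28), 2 fell, CCL11 and the cytokine signalling inhibitor CISH (-0.07, SE 0.016, adjusted p = 0.0424), 6 did so adjusted over the list alone, and 12 had negative differences. Camera gave adjusted p = 0.000274, and adjusted p = 0.0284 with an estimated correlation. IL13RA2, the IL-13 decoy receptor, differed by -0.13 (SE 0.034, adjusted p = 0.141) and SOCS1, a feedback inhibitor of the same pathway, by -0.097 (SE 0.027, adjusted p = 0.275). With the run as a block these adjusted p-values were 0.00501 and 0.00713. The call of CISH ended when any of 36 of the 54 arrays was left out, with a highest adjusted p of 0.0857, as well as under quantile normalization (0.0705) and without a filter (0.0519). The collagen genes that IL-13 is known to act on through TGF-beta did not pass the test, with COL1A1 at -0.047 (adjusted p = 0.979), COL1A2 at 0.01 and COL3A1 at -0.007, nor did POSTN (0.014) or TIMP1 (0.01).

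Other lists shifted with the label with few or no members past the threshold. The 14 tested p53 targets were higher as a set (adjusted p = 0.00336, and adjusted p = 0.0182 with an estimated correlation), with 0 called and 10 positive. Collagen modification enzymes were lower in 13 of 13 members (adjusted p = 0.00835, and adjusted p = 0.0619 with an estimated correlation), a call that ended without vehicle without IL-13 at 4 h replicate 3 (adjusted p = 0.085). The NRF2 oxidative stress list was lower (adjusted p = 0.0178, and adjusted p = 0.0576 with an estimated correlation), and 6 arrays could each end that call, with a highest p of 0.088. Among its members GCLM, a subunit of the enzyme that starts glutathione synthesis, differed by -0.12 (adjusted p = 0.979, and 0.00298 with the run as a block). Immediate early genes were higher (adjusted p = 0.00835, and adjusted p = 0.619 with an estimated correlation), a call that ended without CBNP without IL-13 at 48 h replicate 1 (adjusted p = 0.0551) or CBNP with IL-13 at 48 h replicate 3 (adjusted p = 0.0877). The unfolded protein list was called higher with the run as a block (adjusted p = 0.0154) and not without it (adjusted p = 0.219). Each of the other 19 lists had an adjusted p of at least 0.142.

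In vehicle cells taken at single times, with 3 arrays against 3, limma called 0 genes for the IL-13 label at 4, 24 or 48 h. At an unadjusted p under 0.05 there were 197, 34 and 407 genes, and with the run as a block 2, 3 and 3 were called, all lower. CCL11 means at 4 h were 0.86 (SD 0.22) without and 0.045 (SD 0.29) with the label. The adjusted p of CCL11 was 1, 1 and 0.913 at the 3 times, and 6.28e-09, 0.000787 and 0.000669 with the run as a block. At 48 h 1 gene was called when vehicle with IL-13 at 48 h replicate 1 was left out. The IL-13 and STAT6 list was lower at 4 h (adjusted p = 0.000698, and adjusted p = 0.0593 with an estimated correlation) and at 24 h (adjusted p = 0.0244, and adjusted p = 0.192 with an estimated correlation). The call at 4 h ended without vehicle without IL-13 replicate 1 (adjusted p = 0.131) or vehicle with IL-13 replicate 2 (0.113). The call at 24 h ended without vehicle with IL-13 replicate 1 (0.0537) or 2 (0.142) or vehicle without IL-13 replicate 1 (0.145) or 3 (0.115). At 48 h 0 lists were called. The NRF2 list was lower at 4 h (adjusted p = 0.00197, and adjusted p = 0.0228 with an estimated correlation), a call that ended without vehicle without IL-13 at 4 h replicate 3 (adjusted p = 0.0586). The p53 list was higher at 24 h (adjusted p = 0.00136, and adjusted p = 0.00575 with an estimated correlation).

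MWCNT lowered LXN, CXCL12, FAP and ITGA4, among other genes. Over both labels and all times, LXN (latexin), a carboxypeptidase inhibitor, fell from 1.16 in vehicle to 0.79 in MWCNT cultures, a difference of -0.37 (SE 0.037, n = 18 arrays each, adjusted p = 1.92e-08). That is 1.29-fold lower if the base is 2 and 1.44-fold if it is e. CXCL12, the stromal chemokine that binds CXCR4, fell by 0.23 (SE 0.033, adjusted p = 6.53e-05), FAP, a serine protease of activated fibroblasts, by 0.21 (SE 0.044, adjusted p = 0.0191). ITGA4, an integrin subunit that binds fibronectin and VCAM1, fell by 0.19 (SE 0.037, adjusted p = 0.00434), and PDGFD, a ligand of PDGF receptor beta, by 0.18 (SE 0.035, adjusted p = 0.00752). Also lower were the bradykinin receptor BDKRB1 (-0.13, adjusted p = 6.53e-05) and the retinoic acid-inducible receptor GPRC5A (-0.19, adjusted p = 6.53e-05). So were the CDC42 effector CDC42EP3 (-0.21, adjusted p = 0.0108), the stem cell factor receptor KIT (-0.2, adjusted p = 0.0223) and the BMP-family factor GDF5 (-0.13, adjusted p = 0.0318). Among the genes that rose were the co-chaperone DNAJB2 (0.15, SE 0.035, adjusted p = 0.0439), the cytoskeletal NAV2 (0.13, SE 0.028, adjusted p = 0.0238) and the actin-binding MTSS1 (0.097, adjusted p = 0.0441). The ITGA4 call ended with the mean of its probe sets (adjusted p = 0.0788), and 2 of 4 probe sets of MTSS1 shared its sign.

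In all 10 genes rose and 21 fell with MWCNT (1047 at an unadjusted p under 0.05), 23 of the 31 with the same sign in all 6 conditions, and 212 rose and 120 fell with the run as a block. Centring the arrays on their medians gave 4 rising and 17 falling genes. Without the 3 arrays of doubtful quality 0 rose and 21 fell, and DNAJB2 (adjusted p = 0.16), NAV2 (0.141) and MTSS1 were no longer called. For MTSS1 the highest adjusted p over its alternatives was 0.649, with the mean of its probe sets. Over all alternatives, single arrays left out included, the adjusted p of LXN reached at most 4.92e-07 and that of CXCL12 at most 0.000197. RNA integrity moved with this group, since the ACTB 3' minus 5' difference exceeded 0.3 in 4 of 18 MWCNT arrays, 1 vehicle array and 0 CBNP arrays. The count of 31 moved by more than 1.5 times when 1 of 14 arrays was left out. It was 16 without vehicle without IL-13 at 48 h replicate 1, 20 without vehicle with IL-13 at 24 h replicate 1, 19 without vehicle without IL-13 at 24 h replicate 2 or at 4 h replicate 3. It was 18 without MWCNT with IL-13 at 4 or 48 h replicate 2 or MWCNT without IL-13 at 48 h replicate 2. It was 17 without MWCNT without IL-13 at 4 h replicate 2 and 20 without its 24 h replicate 2. It was 83 without vehicle without IL-13 at 48 h replicate 2, 52 without vehicle with IL-13 at 48 h replicate 2. It was 67, 52 and 54 without MWCNT without IL-13 at 48 h replicates 1 and 3 and at 24 h replicate 3. KIT lost its call without vehicle without IL-13 at 48 h replicate 1 (adjusted p = 0.0559). DNAJB2 and MTSS1 each lost theirs with 22 arrays, NAV2 with 4 and GDF5 with 7, the highest adjusted p being 0.0963 for MTSS1.

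By list, aryl hydrocarbon receptor targets were lower with MWCNT in 5 of 5 tested members, with 0 called over all genes and 4 adjusted over the list alone. Their median was -0.084 (camera adjusted p = 0.000329, and adjusted p = 0.0286 with an estimated correlation). CYP1B1, a xenobiotic-metabolising P450 of that list, differed by -0.21 (adjusted p = 0.284, and 2.24e-05 with the run as a block). Chemokines and cytokines were lower as a list of 9 tested members (adjusted p = 0.00776, and adjusted p = 0.123 with an estimated correlation). Of these 1, CXCL12, fell and 2 did so adjusted over the list alone. The 24 tested collagen and matrix genes were lower as a set (adjusted p = 0.00727, and adjusted p = 0.195 with an estimated correlation), with 1, FAP, past the threshold and 19 negative. That call ended without vehicle without IL-13 at 4 h replicate 3 (adjusted p = 0.126). COL1A1 itself differed by -0.013 (adjusted p = 0.944), the smooth muscle actin gene ACTA2 by -0.026 (adjusted p = 0.71), TGFB1 by -0.016 and PDGFA by -0.002. Cholesterol synthesis genes were higher in 15 of 15 members with 0 called and a median of 0.12 (adjusted p = 0.0162, and adjusted p = 0.7 with an estimated correlation). MSMO1 of that pathway differed by 0.28 (adjusted p = 0.6, and 0.0055 with the run as a block). NRF2 targets were lower with 0 called and 4 adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.0802 with an estimated correlation). The interferon list was lower too (adjusted p = 0.0307, and adjusted p = 0.203 with an estimated correlation). The cholesterol and interferon calls could each be ended by 11 of the 54 arrays, with highest p-values of 0.142 and 0.113. With the run as a block the unfolded protein list (adjusted p = 0.0296 against 0.381) and the cell cycle list (0.0165 against 0.097) were called as well. HMOX1, the oxidative stress-induced heme oxygenase, differed by 0.13 (adjusted p = 0.449).

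At single times MWCNT against vehicle gave few genes with 3 arrays a group. LXN fell at 24 h without the IL-13 label (-0.53, SE 0.091, adjusted p = 0.00821), at 24 h with it (-0.5, SE 0.091, adjusted p = 0.0181) and at 48 h without it (-0.54, SE 0.091, adjusted p = 0.0041). There GALNT12, an enzyme that starts mucin-type O-glycosylation, also fell (-0.32, SE 0.056, adjusted p = 0.00464). No other gene passed the test, and limma called 0 at 4 h without (362 at an unadjusted p under 0.05, 0 with the run as a block) and with the label (304, and 0). It also called 0 at 48 h with the label (710, and 1). With the run as a block 13 genes were called at 48 h without the label. A fit of the compared arrays alone called 0 genes at 24 and 48 h without the label, with adjusted p-values for LXN of 0.784 and 0.999, the highest over its alternatives. At 24 h without the label the call of LXN ended without vehicle replicate 1 (adjusted p = 0.16) or 3 (0.0919) or MWCNT replicate 1 (0.677) or 2 (0.0801). At 24 h with the label it ended without any 1 of the 6 arrays, with adjusted p-values from 0.0653 to 0.4, and under quantile normalization (0.0527). At 48 h without the label it ended without MWCNT replicate 2 (adjusted p = 0.167) or vehicle replicate 3 (0.122) and without the 3 arrays of doubtful quality (0.22). That of GALNT12 ended without these (0.0939 and 0.111) or MWCNT replicate 3 (0.0554), while 4 genes were called without vehicle replicate 2. At 48 h with the label 2 genes were called without vehicle replicate 1. Collagen and matrix genes were lower as a list at 4 h without the label (adjusted p = 5.35e-05, and adjusted p = 0.142 with an estimated correlation), a call that ended without vehicle replicate 3 (adjusted p = 0.673). NRF2 targets were lower at 24 h without (adjusted p = 0.00998, and adjusted p = 0.0332 with an estimated correlation) and with the label (adjusted p = 0.00672, and adjusted p = 0.0413 with an estimated correlation). These NRF2 calls ended without MWCNT replicate 3 without the label (adjusted p = 0.122) and MWCNT replicate 2 with it (0.104).

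CBNP lowered LXN, GPRC5A and BDKRB1, as MWCNT did, and raised GEM and HMOX1. LXN fell from 1.16 to 0.84 (-0.32, SE 0.037, n = 18 arrays each, adjusted p = 4.5e-07). That is 1.25-fold lower if the base is 2 and 1.37-fold if it is e. MGLL, which hydrolyses monoacylglycerols, fell by 0.23 (SE 0.028, adjusted p = 4.5e-07), BDKRB1 by 0.18 (SE 0.019, adjusted p = 1.24e-07) and GPRC5A by 0.2 (SE 0.027, adjusted p = 1.05e-05). The chondroitin sulfotransferase CHST15 fell by 0.23 (SE 0.037, adjusted p = 0.000389) and the chemokine-scavenging receptor ACKR4 by 0.25 (SE 0.057, adjusted p = 0.0208). GEM, a small GTPase that limits calcium channel activity, rose by 0.33 (SE 0.068, adjusted p = 0.00628) and HMOX1 by 0.35 (SE 0.067, adjusted p = 0.00302), the latter in 5 of 6 conditions. The antiproliferative BTG1 (0.2, adjusted p = 0.00163), the insulin receptor substrate IRS2 (0.15, adjusted p = 0.0107) and the ubiquitin ligase CBLB (0.15, adjusted p = 0.000389) rose as well. So did the p53-induced phosphatase PPM1D (0.13, adjusted p = 0.0125), the secreted protease ADAMTS1 (0.19, adjusted p = 0.042), NAV2 (0.17, adjusted p = 0.000389) and MTSS1 (0.15, adjusted p = 0.000255). The call of ADAMTS1 ended without the 3 arrays of doubtful quality (adjusted p = 0.0636) and when any of 23 arrays was left out, with a highest p of 0.0942. That of MTSS1 ended with the mean of its probe sets (adjusted p = 0.207), 3 of 4 of which shared its sign.

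In all 29 genes rose and 44 fell with CBNP (800 at an unadjusted p under 0.05), 53 of the 73 with the same sign in all 6 conditions, and 131 rose and 189 fell with the run as a block. Centring the arrays on their medians gave 18 rising and 43 falling genes, and with the RNA integrity covariates 70 rose and 82 fell. The count was 48 without vehicle without IL-13 at 48 h replicate 1 or CBNP with IL-13 at 48 h replicate 2, and 45 without CBNP with IL-13 at 24 h replicate 2. The highest adjusted p over all alternatives, single arrays left out included, was 2.35e-06 for LXN, 0.0154 for GEM and 0.00944 for HMOX1.

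Contractile genes were lower as a list with CBNP, in 13 of 14 tested members with a median of -0.062 (camera adjusted p = 1.64e-06, and adjusted p = 0.0131 with an estimated correlation). TAGLN, the actin-binding transgelin, was the 1 member that fell (-0.18, SE 0.046, adjusted p = 0.0355), and 3 fell adjusted over the list alone. The TAGLN call ended without the 3 arrays of doubtful quality (adjusted p = 0.0725) and without any of 20 single arrays, with a highest p of 0.0839. ACTA2 differed by -0.023 (adjusted p = 0.896). Collagen and matrix genes were lower in 19 of 24 members (adjusted p = 0.000618, and adjusted p = 0.0642 with an estimated correlation). The fibrillin FBN2 (-0.16, adjusted p = 0.0438) was the 1 past the threshold, and 5 fell adjusted over the list alone. The FBN2 call ended without a filter (adjusted p = 0.0572), with the mean of its probe sets (0.267, the highest over its alternatives) and without any of 27 arrays, with a highest p of 0.1. COL1A1 differed by -0.054 (adjusted p = 0.83). The serum response and actin list was lower (adjusted p = 0.00439, and adjusted p = 0.0642 with an estimated correlation). Collagen modification was lower as well (adjusted p = 0.0476, and adjusted p = 0.135 with an estimated correlation), which 22 of 54 arrays could each end, with a highest p of 0.209. TGFBR2, a TGF-beta receptor, fell by 0.11 (adjusted p = 0.00806), though not with the mean of its probe sets (adjusted p = 0.684), and the TGF-beta list was not called (adjusted p = 0.0741).

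Cholesterol synthesis genes were higher with CBNP in 15 of 15 tested members, with a median of 0.15 and 0 past the threshold. Camera gave adjusted p = 4.92e-06, and adjusted p = 0.314 with an estimated correlation. Of these members, 10 were called with the run as a block. INSIG1, the sterol-sensing brake on SREBP, differed by 0.45 (SE 0.18, adjusted p = 0.411, and 7.63e-05 with the run as a block), HMGCS1 by 0.35 (adjusted p = 0.509, and 0.000455 with the block) and IDI1 by 0.33 (adjusted p = 0.526, and 1.71e-05 with the block). Of the NRF2 targets HMOX1 rose while the aldo-keto reductases AKR1C1 (-0.11, adjusted p = 0.0237) and AKR1C2 (-0.093, adjusted p = 0.0355) fell, and the list was lower (adjusted p = 0.0153, and adjusted p = 0.0642 with an estimated correlation). AKR1C1 lost its call under quantile normalization (adjusted p = 0.171), with the mean of its probe sets (0.117) and without vehicle without IL-13 at 48 h replicate 1 (0.0527). AKR1C2 lost its call under quantile normalization (0.102), without a filter (0.0533) and without any of 17 arrays, with a highest p of 0.0789. Aryl hydrocarbon receptor targets were lower with 0 called and 1 adjusted over the list alone (adjusted p = 0.00876, and adjusted p = 0.0642 with an estimated correlation). CYP1B1 differed by -0.3 (adjusted p = 0.0909, and 7.74e-09 with the run as a block). The lysosome list was called higher with the run as a block (adjusted p = 0.0482 against 0.0741), and 1 member, the sialidase NEU1, rose (0.1, adjusted p = 0.0323). The NEU1 call ended without the 3 arrays of doubtful quality (adjusted p = 0.0699), with median-centred arrays (0.0567) and without any of 12 arrays, with a highest p of 0.0693.

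Chemokines and cytokines were lower as a list with CBNP (camera adjusted p = 0.0023, and adjusted p = 0.0642 with an estimated correlation). The IL-6-family cytokine LIF (-0.15, adjusted p = 0.0323) was the 1 member past the threshold, a call that ended without any of 16 arrays (highest p 0.0695). CCL2, the monocyte chemokine, differed by -0.31 (adjusted p = 0.191, and 0.00012 with the run as a block), CCL11 by -0.36 (adjusted p = 0.081, and 2.36e-10 with the block) and IL6 by -0.14 (adjusted p = 0.6, and 6.43e-05 with the block). Over the alternatives other than single arrays left out, the adjusted p ran from 6.98e-06 to 0.24 for CCL2 and from 2.36e-10 to 0.107 for CCL11. With single arrays left out in turn it reached 0.336 for CCL2 and 0.174 for CCL11. The IL-13 and STAT6 list was lower (adjusted p = 0.00316, and adjusted p = 0.0642 with an estimated correlation). Of 18 members 1 was past the threshold, the receptor chain IL4R (-0.091, adjusted p = 0.0355), whose call ended without any of 17 arrays (highest p 0.079). The interferon list was lower in 14 of 17 members with 0 called (adjusted p = 0.0023, and adjusted p = 0.0642 with an estimated correlation). So was the cell cycle list with 0 of 26 called (adjusted p = 0.0367, and adjusted p = 0.639 with an estimated correlation), which 16 arrays could each end, with a highest p of 0.202. Not called were NF-kB feedback (adjusted p = 0.915), matrix proteases (0.913), growth factors (0.578), metallothioneins (0.205), unfolded protein (0.739), heat shock (0.828) and p53 (0.0741). Nor were immediate early genes (0.143), hypoxia (0.477) and the epithelial (0.731), endothelial (0.412) and leukocyte markers (0.847). DUSP6, the ERK phosphatase of the immediate early list, fell by 0.17 (adjusted p = 0.00462).

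**Figure D2:**
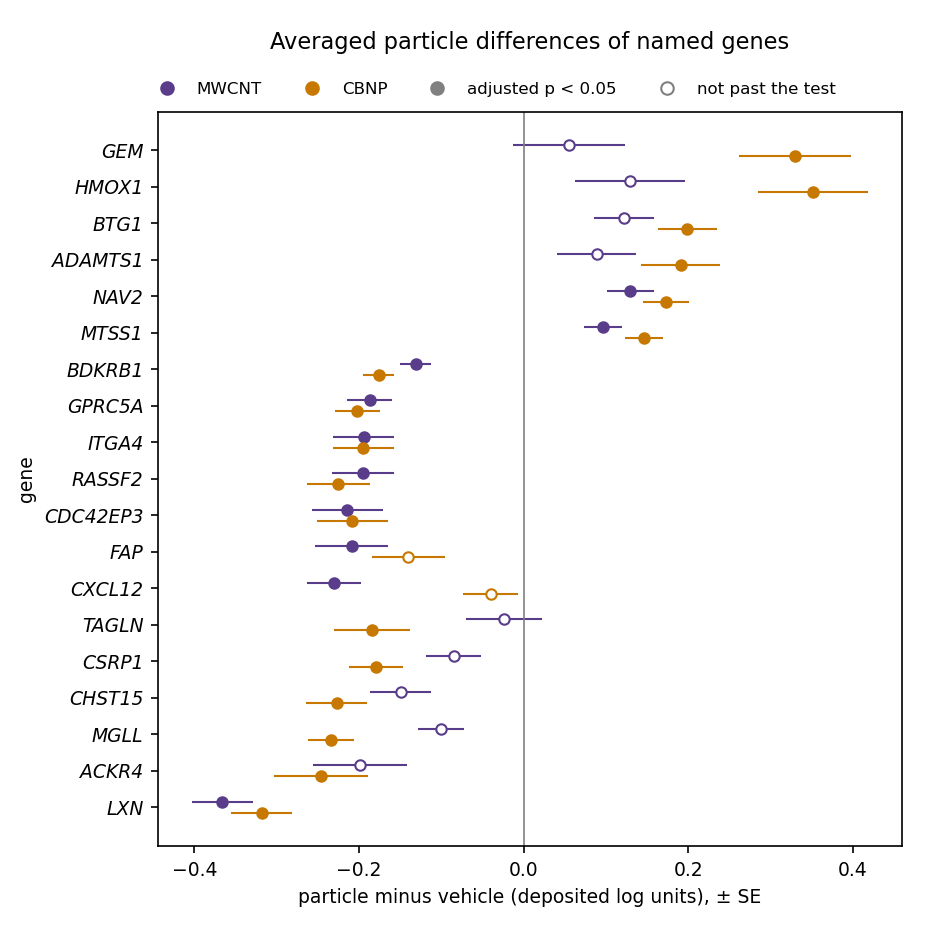
Difference from vehicle in deposited log units (x axis) of 19 genes (y axis) for MWCNT and CBNP averaged over both IL-13 labels and 3 times, with bars of 1 SE (n = 18 arrays each), filled where the adjusted p is under 0.05. LXN lies at -0.37 for MWCNT and -0.32 for CBNP, and GEM at 0.33 for CBNP.

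At single times CBNP without the IL-13 label lowered LXN at 48 h (-0.53, SE 0.091, adjusted p = 0.00165), with GPRC5A (-0.44, SE 0.067, adjusted p = 0.000561), MGLL (-0.4, SE 0.068, adjusted p = 0.00165) and GALNT12 (-0.33, SE 0.056, adjusted p = 0.00165). At 4 h with the label it lowered IER3, an immediate early response gene (-0.31, SE 0.062, adjusted p = 0.0411), and BDKRB1 (-0.24, SE 0.047, adjusted p = 0.0411). The other times gave 0 genes, namely 4 h without the label (387 at an unadjusted p under 0.05, 4 with the run as a block), 24 h without it (199, and 7), 24 h with it (103, and 0) and 48 h with it (208, and 31). At 48 h without the label 63 genes were called with the block, 8 without vehicle replicate 3, and MGLL lost its call without CBNP replicate 2 (adjusted p = 0.0878). In a fit of the compared arrays alone, the adjusted p at 48 h was 0.126 for LXN, 0.0776 for GPRC5A, 0.275 for MGLL and 0.062 for GALNT12, the highest over their alternatives. At 4 h with the label IER3 lost its call without vehicle replicate 1 (adjusted p = 0.0664), 2 (0.329) or 3 (0.999) or CBNP replicate 1 (0.292) or 2 (1). BDKRB1 lost it without vehicle replicate 1 (0.731), 2 (0.329) or 3 (0.0809) or CBNP replicate 2 (1) or 3 (0.364). Both lost it without a filter (0.0648), and 5 genes were called with the block. CBNP without IL-13 at 4 h replicate 1, left out, gave 1 gene at 4 h without the label, and CBNP with IL-13 or vehicle with IL-13 at 48 h replicate 1 gave 1 gene at 48 h with it.

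**Figure D3:**
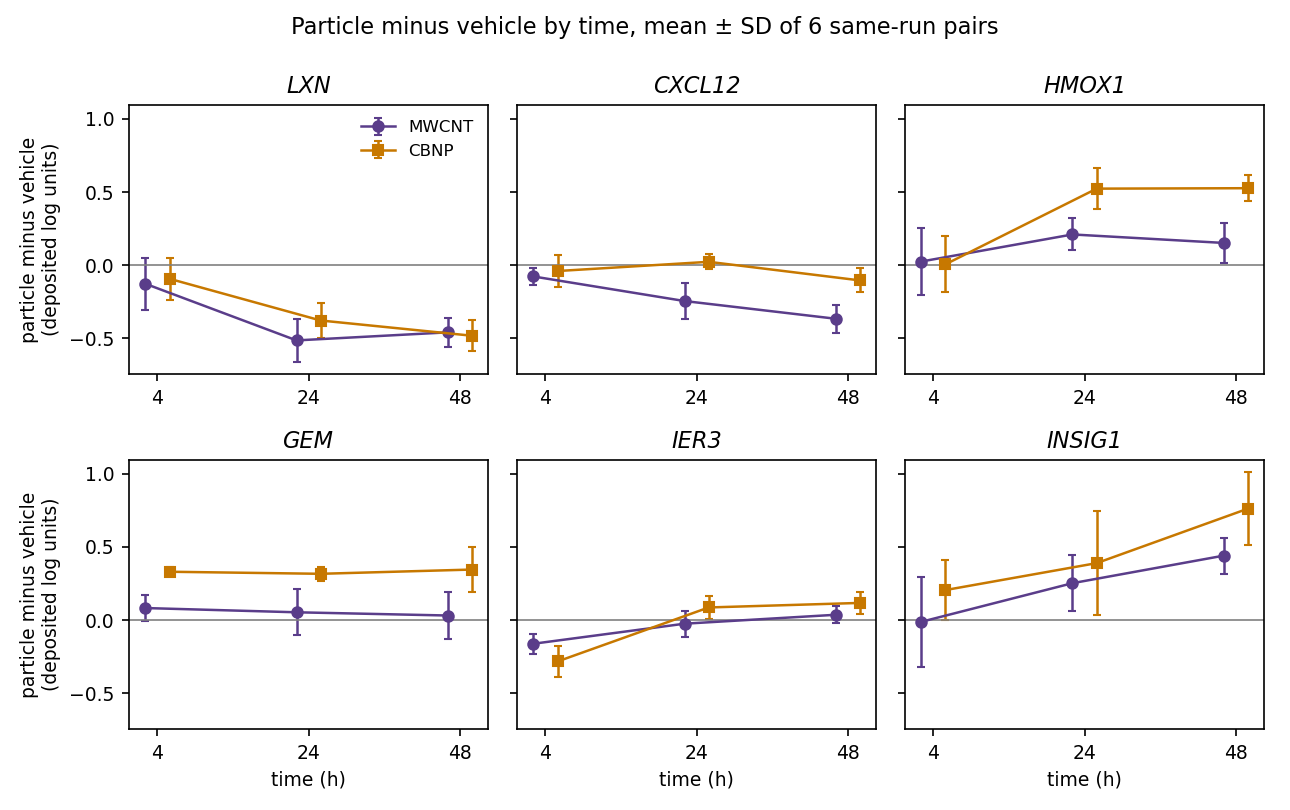
Mean difference from vehicle in deposited log units (y axis, bars of 1 SD over 6 same-run pairs) of LXN, CXCL12, HMOX1, GEM, IER3 and INSIG1 at 4, 24 and 48 h (x axis) for MWCNT and CBNP. With CBNP, HMOX1 lies at 0.006, 0.52 and 0.53 and GEM at 0.33, 0.32 and 0.35 at the 3 times.

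MWCNT and CBNP, compared directly at the same dose, differed in CXCL12. It was 1.87 with MWCNT and 2.06 with CBNP, a difference of -0.19 (SE 0.033, n = 18 arrays each, adjusted p = 0.00999) that was negative in 6 of 6 conditions, from -0.33 to -0.009. With the RNA integrity covariates its adjusted p was 0.0673, the highest over its alternatives, and no array left out alone ended the call. It was the 1 gene called (760 at an unadjusted p under 0.05), against 47 higher and 18 lower with the run as a block and 8 higher and 5 lower after quantile normalization. CCL11 (0.3, adjusted p = 0.393, and 9.1e-08 with the block), CCL2 (0.26, adjusted p = 0.519, and 0.006 with the block) and HMOX1 (-0.22, adjusted p = 0.299, and 0.0141 with the block) passed only with the block. Contractile genes were higher with MWCNT than with CBNP in 12 of 14 members with 0 called and 2 adjusted over the list alone (adjusted p = 0.00826, and adjusted p = 0.398 with an estimated correlation). Cholesterol synthesis was lower with MWCNT than with CBNP with the run as a block (adjusted p = 0.005) and not called without it (adjusted p = 0.285). Each of the other 23 lists had an adjusted p of at least 0.088. The count of 1 rose to between 2 and 12 when any of 24 arrays was left out, with 12 without MWCNT without IL-13 at 48 h replicate 1.

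Of the 21 genes lower with MWCNT and the 44 lower with CBNP, 12 were shared, among them LXN, GPRC5A, BDKRB1, ITGA4, RASSF2, CDC42EP3, KIT and GDF5, against 0.106 for independent lists of these sizes. With the mean of its probe sets ITGA4 was called for neither particle (adjusted p = 0.0788 with MWCNT and 0.214 with CBNP), and under quantile normalization GDF5 was not called with MWCNT (0.0604). Of the 10 and 29 higher genes 4 were shared, including NAV2 and MTSS1, against 0.0332. Without the 3 arrays of doubtful quality 0 genes rose with MWCNT, which leaves no higher gene to share. With the mean of its probe sets MTSS1 was called for neither particle (limma adjusted p = 0.649 with MWCNT and 0.207 with CBNP). Fitted with the run as a block, 65 of 120 and 189 lower genes were shared (2.6 for independent lists) and 49 of 212 and 131 higher genes (3.18). Both particles were compared with the same vehicle arrays, which raises any such overlap. Over all genes the averaged differences correlated across genes with r = 0.583, against 0.453 (-0.234 to 0.919 over 100 draws) for simulated groups with no effect, with a covariance of 0.00101 against 0.000281. With MWCNT and CBNP each set against other vehicle arrays, r was 0.383 and 0.417, inside the ranges of -0.634 to 0.547 and -0.583 to 0.635 (means -0.072 and -0.0637) for simulated groups with no effect. The first arrangement sets MWCNT with the IL-13 label beside CBNP without it, and the second the reverse. Of the 2 and 12 lower genes 2 were shared in the first (0.00275 for independent lists), and of the 4 and 3 in the second 1 was (0.00137). The run as a block gave 14 shared of 23 and 68 in the first (0.179) and 14 of 23 and 32 in the second (0.0842). MWCNT gave 0 higher genes in either arrangement, so no overlap of higher genes could be seen there, and with the run as a block 1 of 3 and 26 was shared in the first (0.00893) and 1 of 4 and 22 in the second (0.0101). Genes are not independent replicates, and part of the overlap may come from the shared vehicle arrays.

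Whether the IL-13 label changed the response to either particle was tested by the interaction over the 3 times. For MWCNT limma called 0 genes (88 at an unadjusted p under 0.05, 0 with the run as a block), and the smallest unadjusted limma p-values were 0.00345 for KIAA1614 and 0.00402 for CHRNE, an acetylcholine receptor subunit. For CBNP it also called 0 genes (25, and 0 with the block), and the smallest unadjusted limma p-values were 0.00319 for CISH and 0.00475 for HK1, a hexokinase. Each of these genes had an adjusted p of 1.

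In vehicle cells labelled without IL-13, more genes differed between times than between either particle and vehicle. What in the time course caused these changes was not tested. NQO1, the quinone reductase of the NRF2 response, changed by the largest amount at 48 h. NQO1 fell from 2.7 at 4 h to 1.37 at 48 h (-1.32, SE 0.092, n = 3 arrays each, adjusted p = 9.99e-14). That is 2.5-fold lower if the base is 2 and 3.75-fold if it is e. At 24 h it fell by 0.68 (SE 0.092, adjusted p = 9.74e-06). HMOX1 fell by 0.68 at 48 h (adjusted p = 0.00331), and the urea cycle enzyme ASS1 (-0.8, adjusted p = 2.76e-07) and the PCNA-binding PCLAF (-0.82, adjusted p = 0.000132) fell too. The glucose transporter SLC2A3 rose by 0.59 at 24 h (adjusted p = 0.000977) and 0.92 at 48 h (adjusted p = 1.96e-07), and ALDH1A3, which makes retinoic acid, by 0.8 and 0.73 (adjusted p = 0.001 and 0.00086). The matricellular CCN2 rose by 0.59 at 24 h (adjusted p = 2.58e-05), the prostaglandin receptor PTGER4 by 0.55 and 0.8 (adjusted p = 0.031 and 0.000282), and the neutral endopeptidase MME (0.75, adjusted p = 0.000108), the prostacyclin synthase PTGIS (0.82, adjusted p = 0.00102) and IL6 (0.63, adjusted p = 0.0136) at 48 h. At 24 h the PTGER4 call ended without the 3 arrays of doubtful quality (adjusted p = 0.201), without 24 h replicate 1 (0.146) or 2 (0.141) and without 4 h replicate 3 (0.274). In a fit of the compared arrays alone the calls at 24 h of PTGER4, NQO1 (adjusted p = 0.12), ALDH1A3 (0.0569), SLC2A3 (0.0861) and CCN2 (0.0581) ended. At 24 h 189 genes rose and 123 fell, and at 48 h 808 rose and 616 fell, with 616 and 397, and 1343 and 1065, with the run as a block. Centring the arrays on their medians gave 104 rising and 154 falling genes at 24 h, and quantile normalization 172 and 196.

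NRF2 targets were lower as a list at 24 h in 17 of 18 members, with 5 past the threshold and 9 adjusted over the list alone (camera adjusted p = 2.79e-12, and adjusted p = 3.24e-07 with an estimated correlation). At 48 h they were lower with 11 past the threshold and 13 adjusted over the list alone (adjusted p = 2.26e-11, and adjusted p = 7.48e-07 with an estimated correlation). Immediate early genes were higher at 24 h with 4 past the threshold (adjusted p = 3.84e-05, and adjusted p = 0.283 with an estimated correlation) and at 48 h with 6 (adjusted p = 0.00109, and adjusted p = 0.491 with an estimated correlation). At 48 h the hypoxia and glycolysis list was higher with 7 past the threshold (adjusted p = 0.00622, and adjusted p = 0.491 with an estimated correlation), ending without vehicle without IL-13 at 4 h replicate 1 (adjusted p = 0.145). The TGF-beta list was higher with 5 (adjusted p = 0.0225, and adjusted p = 0.0411 with an estimated correlation), ending without 4 h replicate 2 (adjusted p = 0.0812). Cell cycle genes were lower at 48 h with 7 past the threshold (adjusted p = 0.0237, and adjusted p = 0.759 with an estimated correlation) and at 24 h with 2 (adjusted p = 0.0243, and adjusted p = 0.698 with an estimated correlation). The call at 48 h ended without 4 h replicate 2 (adjusted p = 0.345) or 48 h replicate 3 (0.305), and that at 24 h ended without 24 h replicate 1 (0.149) or 3 (0.172) or 4 h replicate 2 (0.417). Metallothioneins were lower at 24 h with 0 past the threshold (adjusted p = 0.0243, and adjusted p = 0.283 with an estimated correlation), ending without 24 h replicate 1 (adjusted p = 0.109) or 4 h replicate 3 (0.256). With the run as a block, collagens (adjusted p = 0.0178 against 0.0757) and cholesterol synthesis (0.00356 against 0.197) were also called at 48 h. The count of 312 genes at 24 h was 603 and 124 without 4 h replicates 1 and 3, and 186 and 159 without 24 h replicates 1 and 3, with 24 h replicate 2 between 124 and 159. It was 4 in a fit of these 6 arrays alone. The 1424 genes at 48 h were 768 without 48 h replicate 2, 928 without 4 h replicate 3 and 522 in a fit of these arrays alone.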

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

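Chosen after the results were seen were the tests of particle effects at 48 h minus 4 h, the CCL11 gap between labels, and those of exchanged labels, wrongly labelled arrays, RNA integrity for CCL11, an equal loss of CCL11 and a CCL11 floor.

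A pair of genes differed between times in their response to CBNP, by limma's test of the effect at 48 h minus that at 4 h. IER3 was lower with CBNP at 4 h (-0.28, mean of 6 same-run pairs) and not at 48 h (0.12), a difference of 0.4 (adjusted p = 0.000944), which stayed at or below an adjusted p of 0.00478 with any array left out. GALNT12 went the other way, from 0.003 at 4 h to -0.29 at 48 h, a difference of -0.294 (adjusted p = 0.0241). Its call ended without the 3 arrays of doubtful quality (adjusted p = 0.0545) and without each of CBNP without IL-13 at 4 h replicate 1 (0.084) or 2 (0.067) and at 48 h replicate 3 (0.086), CBNP with IL-13 at 4 h replicate 3 (0.0694) and at 48 h replicate 2 (0.0904), vehicle with IL-13 at 4 h replicate 2 (0.0688) and at 48 h replicate 2 (0.0532), and vehicle without IL-13 at 4 h replicate 3 (0.0659). CBNP gave 2 such genes and MWCNT 0 (343 at an unadjusted p under 0.05, 1 with the run as a block), and CBNP 55 with the block. Among these 55 were LIF, GPRC5A and KIT, called above in averages over the times. With CBNP, LIF was -0.326 at 4 h and -0.085 at 48 h (limma adjusted p = 0.00406 with the block). GPRC5A was -0.043 and -0.348 (0.00404), and KIT -0.011 and -0.376 (0.00233). IER3 and GALNT12 moved in the same direction with MWCNT without passing limma's test. There GALNT12 went from -0.017 at 4 h to -0.273 at 48 h, a difference of -0.256 (adjusted p = 0.405). IER3 went from -0.162 to 0.036, a difference of 0.198. Whether these time courses differ between the particles was not tested. Of 100 arrangements of the exposure labels, the real one among them, 2 gave as many as the 2 genes for CBNP, with a highest other of 327, and all 100 reach the 0 for MWCNT whatever the data, with a highest other of 369. The arrangements that called 327 and 369 point to a structure of the arrays, and its cause was not tested for these effects.

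IL-13 targets lower in the arrays labelled with IL-13 was the first pattern weighed. Wrong labels on a few arrays are argued against by CCL11 being lower in the labelled array in 27 of 27 pairs. RNA integrity is argued against by the CCL11 difference of -0.449 (SE 0.075, adjusted p = 0.000624) with the ACTB and GAPDH differences as covariates, against -0.454 without. An exchange of the with and without labels over the whole series stays open, as the 15 other tested members of the list were also lower as a set (camera p = 0.0308 by limma, 9 of 15 negative, median -0.017), though with an estimated correlation p was 0.0627. A biological lowering of these genes by IL-13 in this line was not tested and is not excluded. No direction of the IL-13 response is therefore drawn here.

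CCL11 differed less between the labels with CBNP at 24 and 48 h, the second pattern. With MWCNT the label difference was also smaller than in vehicle. CCL11 means without and with the label were 0.963 and 0.689 in MWCNT and 1.171 and 0.66 in vehicle cultures at 24 h. At 48 h they were 1.316 and 1.003 in MWCNT and 1.44 and 0.925 in vehicle cultures. CBNP minus vehicle was -0.63 without and -0.23 with the label, a gap of -0.401 (SD 0.26, below 0 in 6 of 6 run and time pairs, exact two-sided sign-flip p = 0.0312, the smallest that 6 pairs can give), with p = 0.0625 after quantile normalization. On the log scale an equal lowering by CBNP in both label states would leave the label difference unchanged. Such a lowering could therefore not account for a smaller label difference. The gap of -0.401 is the pattern itself, measured in the gene in which it was seen. It is thus no independent test of the pattern or of an equal lowering. A floor is argued against by the mean of 0.615 (SD 0.3, n = 12) in these CBNP arrays, above the 0.045 (SD 0.29, n = 3) at which a label difference was measured at 4 h in vehicle. A loss of the IL-13 signal with CBNP at later times, beyond CCL11, is a hypothesis. For it, 50 genes other than CCL11 were chosen at 4 h by their label difference in vehicle and MWCNT arrays, without CBNP arrays. At 24 and 48 h their oriented label difference was 0.088 in vehicle and 0.014 in CBNP arrays, a gap of 0.074 (SD 0.061, 6 of 6 pairs, exact sign-flip p = 0.0312). The choice itself favours vehicle over CBNP. The label difference of these genes in CBNP arrays at 4 h was not computed, so the gap does not show a loss over time. MWCNT arrays, also used for the choice, had 0.034, and the interaction test called 0 genes for CBNP. Whether there is such a loss, its size, and whether it is particular to CBNP stay open. The 6 pairs behind both sign-flip tests are the 3 runs at 24 and 48 h. Arrays of a run deviated together, so the pairs may not be independent and both p-values may be too small.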

How the results depend on the processing

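Counts of genes called are given as main value to alternative for each result that moved by more than 1.5 times, and the cause was not tested. With the run as a block, CBNP without IL-13 went from 0 to 4 at 4 h, 0 to 7 at 24 h and 4 to 63 at 48 h, and CBNP with IL-13 from 2 to 5 at 4 h and 0 to 31 at 48 h. MWCNT went from 2 to 13 without and 0 to 1 with IL-13 at 48 h. The IL-13 label in vehicle went from 0 to 2, 3 and 3 at 4, 24 and 48 h. The averaged counts went from 15 to 49 for the label, 31 to 332 for MWCNT, 73 to 320 for CBNP and 1 to 65 for MWCNT against CBNP. Time went from 312 to 1013 at 24 h and 1424 to 2408 at 48 h, and the effects at 48 h minus 4 h from 0 to 1 for MWCNT and 2 to 55 for CBNP. Of 130 gene results refitted, 30 that had not been called were called with the block, and it ended 3 gene list calls at single times. Not all genes whose call the block changed are named in the text. With the RNA integrity covariates, the label gave 1 at 4 h and 24 averaged. CBNP gave 1 at 4 h with IL-13, 1 at 24 h without, 3 at 48 h with, 152 averaged and 10 for 48 h minus 4 h. MWCNT against CBNP gave 0, where CXCL12 was no longer called, and 24 h against 4 h gave 676. With both block and covariates, the label gave 12, 3 and 5 at 4, 24 and 48 h and 74 averaged. MWCNT gave 3 at 24 h and 7 at 48 h without IL-13, 2 at 24 h and 9 at 48 h with it, 267 averaged and 4 for 48 h minus 4 h. CBNP gave 12, 13 and 91 at the 3 times without IL-13, 6 at 4 h and 60 at 48 h with it, 628 averaged and 101 for 48 h minus 4 h. MWCNT against CBNP gave 49, and time 1561 and 2919. After quantile normalization CBNP with IL-13 gave 0 at 4 h, where IER3 and BDKRB1 were no longer called, and 2 at 48 h. MWCNT with IL-13 at 24 h gave 0, where LXN was no longer called, MWCNT against CBNP 13 and CBNP at 48 h minus 4 h 4. Without a filter CBNP with IL-13 at 4 h gave 0. With the mean of all probe sets the label gave 1 at 4 h, MWCNT against CBNP 4 and CBNP at 48 h minus 4 h 5. The stricter filter gave 3, and eBayes without trend 3, for MWCNT against CBNP. Without the 3 arrays of doubtful quality CBNP with IL-13 at 4 h gave 0, MWCNT without IL-13 at 48 h 1, MWCNT against CBNP 3 and 24 h against 4 h 177. A fit of the compared groups alone gave 0 for CBNP with IL-13 at 4 h and for MWCNT without IL-13 at 24 and 48 h, and 4 and 522 for time. Leaving out 1 array gave 0 to 1 for CBNP without and with IL-13 at 4 h, 0 to 1 for MWCNT without IL-13 at 24 h, 0 for MWCNT with IL-13 at 24 h, and 0 to 1 for the label at 48 h. At 48 h it gave 0 to 4 for MWCNT and 3 to 8 for CBNP without IL-13, and 0 to 2 and 0 to 1 with it. Averaged counts ran from 16 to 83 for MWCNT, 45 to 86 for CBNP and 1 to 12 for MWCNT against CBNP. Time ran from 124 to 603 and 768 to 1566, and the effects at 48 h minus 4 h from 0 to 1 for MWCNT and 1 to 6 for CBNP. Of 108 calls of gene lists 15 remained with an estimated correlation, and of the 99 outside the time comparisons 12. No gene that was refitted reversed its direction, and no list did with the block, the estimated correlation or an array left out, the settings run for lists. Median-centred arrays moved no total by more than 1.5 times, but the rising genes went from 10 to 4 for MWCNT, 29 to 18 for CBNP and 189 to 104 for 24 h. Leaving out 1 array of 3 assumes that the rest vary like the other groups.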

Other observations

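The test of retinoid-responsive genes used a list added after values of LXN, GPRC5A, RARRES1, DHRS3 and CRABP2 had been seen, and chosen without these genes. The particle effects at 48 h minus 4 h were also examined only after the results were seen.

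Contractile and heat shock genes shifted as lists with CBNP at 48 h, where limma called 0 genes with the IL-13 label (208 at an unadjusted p under 0.05, 31 with the run as a block). With that label, contractile genes were lower in 14 of 14 tested members (camera adjusted p = 9.27e-06, and adjusted p = 0.0189 with an estimated correlation), and heat shock genes were higher in 9 of 9 (adjusted p = 0.0031, and adjusted p = 0.0189 with an estimated correlation), a call that ended without vehicle with IL-13 at 48 h replicate 3 (adjusted p = 0.0764). At 24 h without the label NRF2 targets were lower in 15 of 18 members (adjusted p = 1.87e-07, and adjusted p = 4.58e-05 with an estimated correlation) while HMOX1 of that list averaged 0.52 above vehicle over both labels, and at 4 h without the label collagens were lower in 20 of 24 (adjusted p = 8.37e-07, and adjusted p = 0.0384 with an estimated correlation), ending without vehicle without IL-13 at 4 h replicate 3 (adjusted p = 0.317). Immediate early genes were lower with CBNP at 4 h with the label (adjusted p = 6.45e-06, and adjusted p = 0.16 with an estimated correlation), ending without vehicle with IL-13 at 4 h replicate 1 (adjusted p = 0.155), and higher at 48 h with it (adjusted p = 9.27e-06, and adjusted p = 0.189 with an estimated correlation), ending without CBNP with IL-13 at 48 h replicate 3 (adjusted p = 0.108). The change of a list's shift between times was not tested.

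Cholesterol synthesis genes were higher with CBNP at 48 h both without (adjusted p = 3.5e-06, and adjusted p = 0.262 with an estimated correlation) and with the label (adjusted p = 4.43e-06, and adjusted p = 0.291 with an estimated correlation). The CBNP difference of INSIG1 averaged 0.2, 0.39 and 0.76 over 6 same-run pairs at 4, 24 and 48 h, and that of IDI1 0.17, 0.26 and 0.56. Epithelial markers, of which 9 are tested, were higher with MWCNT at 4 h with the label in 9 of 9 (adjusted p = 0.00297, and adjusted p = 0.449 with an estimated correlation), ending without MWCNT with IL-13 at 4 h replicate 2 (adjusted p = 0.0804). They were also higher at 24 h with the label in 9 of 9 (adjusted p = 0.0296, and adjusted p = 0.447 with an estimated correlation), ending without MWCNT with IL-13 at 24 h replicate 3 (adjusted p = 0.973) or vehicle with IL-13 at 24 h replicate 1 (0.258) or 2 (0.116). Endothelial markers were lower with CBNP at 48 h with the label in 4 of 4 tested (adjusted p = 0.0268, adjusted p = 0.189 with an estimated correlation and 0.0542 with the run as a block), ending without CBNP with IL-13 at 48 h replicate 1 (adjusted p = 0.0582) or 3 (0.0656) or vehicle with IL-13 at 48 h replicate 3 (0.653). The fibroblasts are a cell line by the labels, so these lists are read as names of genes, and whether other cells were present was not tested. Other calls of lists at single times are not given.

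Genes lower with both particles formed the third pattern. For MWCNT, lower RNA integrity is argued against by limma fits with the ACTB and GAPDH differences as covariates. All 21 lower genes (a share of 1) kept their direction and an unadjusted p under 0.05. They had been chosen in the same arrays at a stricter threshold, so this is a mild test. It was not run for CBNP. There the ACTB 3' minus 5' difference averaged -0.091 (SD 0.096), against -0.04 (SD 0.13) in vehicle arrays (n = 18 each), so by this measure integrity was not lower. Lower retinoid signalling is a candidate explanation, because GPRC5A, RARRES1 (-0.34 with MWCNT and -0.32 with CBNP, named after its values were seen) and LXN are known to respond to retinoic acid. By limma's camera, 14 tested genes of a list of 24 others gave p = 0.775 with MWCNT and 0.25 with CBNP (n = 18 arrays each). The test had set such values as speaking against it, yet a p above the threshold excludes nothing with 14 members that went both ways (7 and 9 negative), so this stays open. Carry-over of particles into the RNA was not tested.

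Other splits of the arrays were refitted for each count of genes. For single times the 6 arrays allow 10 splits, too few for a share under 0.05. The highest count of the other splits was 0 against a real 2 for CBNP with IL-13 at 4 h, 0 against 1 for MWCNT at 24 h in both label states, 0 against 4 for CBNP without IL-13 at 48 h, 0 against 312 and 1424 for 24 and 48 h against 4 h, and 1 split, the real one, reached each of these counts. For MWCNT without IL-13 at 48 h 2 splits reached the real 2 genes, with a highest other of 7, and 0 among splits parting all pairs of a run. Where the real count was 0, all 10 splits reach it whatever the data, with highest others of 1 for each particle without IL-13 at 4 h, 9 for CBNP with IL-13 at 48 h (2 among those parting all pairs) and 0 for the rest.

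For the averaged comparisons 100 splits within conditions were drawn. As many genes as the real split were called in 3 splits for the IL-13 label (real 15, highest other 536) and 2 for MWCNT (31 and 45). The same held in 2 for CBNP (73 and 79) and 1 for MWCNT against CBNP (1 and 0), where the count rests on CXCL12 alone. Each is a share under 0.05. These splits mix the runs and so break the pairing of the arrays, and by themselves they do not exclude chance assignment. Exchanges within runs are the closer test. The split calling 536 genes points to the runs as a structure of the arrays. When labels were exchanged only within runs, which parts as many pairs as the real split, 1 of 100 reached the real count in each of these comparisons, with highest others of 0 for the IL-13 label and MWCNT, 1 for CBNP and 0 for MWCNT against CBNP. With the run as a block it was again 1 of 100 in each, with real counts of 49, 332, 320 and 65 and highest others of 0, 0, 37 and 3. For the interactions the real count was 0, which all 100 splits reach whatever the data, with highest others of 310 for MWCNT and 0 for CBNP, so these splits decide nothing.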
